A study of Rattus norvegicus with 30 samples.

How the data were processed

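The study measured gene expression in the livers of 30 rats with 1 Affymetrix array per animal; the labels call the arrays of a group biological replicates. Animals were grouped by the diet named in the labels, 5 per diet. Total RNA was labelled with biotin as cRNA, per the labels' protocols. The authors deposited 1 intensity per probe set and array, normalized between arrays with the SuperNORM data service per the labels, which list its distribution parameters for each array. How these intensities were returned to a linear scale, and their reference level, is not given in the sources used here, so a fold is relative to that unstated scale. C replicate 3 and CI replicate 3 carry the same parameters in the labels. Their values correlate at 0.9663, within the 0.943 to 0.9775 of arrays from different groups. They are thus not copies of each other, and both were kept as separate samples. The correlation cannot show whether either was normalized with the parameters of the other. A deposited text describes a table of p-values from the authors; that table was not used here.

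The table held 31099 probe sets, of which 57 controls were left out. The design had foreseen values already on a log scale, but they are linear intensities from 0 to 129458.5. They were therefore raised to a floor of 16 and log2-transformed; the floor was chosen after the values were seen and before any test. Zero stood in 143 cells of 48 probe sets. A probe set was tested if its mean log2 value over all arrays lay above the 40th percentile, a level of 7.388 (intensity 167.6), which left 18625 probe sets for 10699 genes. Gene symbols came from the platform annotation, in which 20832 probe sets have 1 symbol, 436 several and 9831 none; 20764 of the first were matched to a current gene record and 0 symbols changed. Probe sets with several symbols or none were not named. A gene was represented by its tested probe set with the highest mean. The platform gives no genome build here, so no coordinates are printed.

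Group means of all 30 arrays were fitted with limma 3.58.1 in R 4.3.3, with 24 residual degrees of freedom, a mean-variance trend in the empirical Bayes step and two-sided tests. Benjamini-Hochberg adjustment ran over all tested probe sets within each of 9 comparisons, with a threshold of 0.05, and a moderated F test covered all diets. Lists of 16 gene groups and 11 cell types were fixed before the data were examined, as were the design, the alternatives other than those named below and the rule for named genes. Of 661 list entries 582 were named on the array, and 489 different genes were tested; the rest were not analysed here. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 27 lists within a comparison. The acute phase list as written mixes genes that rise in inflammation with genes that fall, so its direction is not that of inflammation. With an estimated correlation, the 54 list calls of the 9 comparisons fell to 6, which were fatty acid synthesis, pericentral markers and, for T10 only, xenobiotic metabolism and bile acid metabolism; fry, which tests whether a list moves one way, called 23. Named genes were, per comparison, the 8 most higher and 8 most lower among those passing (or the 3 of smallest p where fewer than 3 passed), up to 4 members per list, and 9 measured genes of a fixed set of 12 lipid genes for tofu and soy protein against casein. Of the list members chosen this way, some whose call depended on 1 array are counted and not named; this was decided after the values were seen.

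Alternatives were quantile normalization, median centring, equal median and spread, no filter or a 60th percentile filter on dim probe sets, no variance trend, only the compared groups, array weights, the replicate number as a block, a threshold of 0.01, a minimum difference of 1 residual SD (0.291), each array left out in turn, and C replicate 3 and CI replicate 3 left out. Floors of 1 and 64, T10 replicates 3, 4 and 5 left out, and replicates 4 and 5 of both tofu groups left out were chosen after seeing the data. The median difference of all probe sets stayed within 0.1 of 0 under each scaling. Simulated data had the real means and spreads of 18625 probe sets, with 200 changed and with noise independent between probe sets. On them the T20 against C test recovered 53.7% of changes of 1.5-fold, 88.1% of 2-fold and 100% of 4-fold, with 7 false calls among 168. Probe sets that move together, as on real arrays, were not simulated. The interaction test recovered 46.3%, 77.6% and 97%. Comparisons with a shared control were set beside simulations of unchanged groups, and chance was examined with up to 100 splits of the arrays. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.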

Results

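Livers of 30 male Sprague-Dawley rats were profiled on 1-colour Affymetrix arrays, with 1 array per animal and 5 animals on each of 6 diets. The casein diet (C) was the control, and CI was the same diet with added isoflavones. Soy protein replaced casein in S, and SI was S with added isoflavones. Freeze-dried tofu supplied all of the 200 g/kg protein in T20, and in T10 tofu and casein each supplied 100 g/kg. Animals were fed for 14 days, and the isoflavone added to CI and SI was set to the level in T20. The median intensity of an array lay between 217.4 and 255.5, and the number of arrays limits the precision. Differences are on the log2 scale of the deposited intensity, given ± SE with 5 animals per group, and adjusted p-values are from limma. The SE of a probe set uses 1 spread estimated over all 6 diets. Across the 6 diets, 2409 of 18625 tested probe sets differed by the moderated F test.

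The first comparison asked how liver expression differed when tofu was the whole protein source. Genes of fatty acid synthesis fell and the paired genes of the hepatic sterol exporter rose with T20. *Pnpla3*, a lipid droplet protein, had a log2 difference from C of -3.96 ± 0.47, *Fasn* (fatty acid synthase) -1.99 ± 0.47 and *Me1* (cytosolic malic enzyme, a source of NADPH) -1.76 ± 0.19. *Abcg8* and *Abcg5*, which together form the transporter that moves sterols into bile, rose by 2.71 ± 0.42 (6.55-fold) and 2.09 ± 0.35 (4.25-fold). The adjusted p was 1.07e-05 for *Pnpla3*, 0.0144 for *Fasn*, 3.09e-06 for *Me1*, 0.000484 for *Abcg8* and 0.00105 for *Abcg5*, and for each gene all 5 T20 livers lay beyond every C liver. The means of *Abcg8*, *Acsm3*, *Slc1a2* and *Pcp4l1* in C lay below the filter level for dim probe sets. *Scd* (stearoyl-CoA desaturase), *Acly* (ATP citrate lyase) and *Acaca* (acetyl-CoA carboxylase) fell as well, at -1.37 ± 0.28, -1.37 ± 0.29 and -1.06 ± 0.18. *Cyp7a1*, the rate-limiting enzyme of bile acid synthesis, had a difference of 1.92 ± 0.59 that did not pass (adjusted p = 0.0566), although it passed without any one of C replicate 4 and T20 replicate 4 (range over arrays left out 0.0161 to 0.196). *Srebf1* at -0.54 ± 0.36 and *Cpt1a* at -0.25 ± 0.29 did not pass either (adjusted p = 0.426 and 0.673).

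In the fatty acid and triglyceride synthesis list, 14 of 25 measured genes fell (16 adjusted over the list alone), with a median of -0.56. The list differed from other genes by camera, with adjusted p = 6.99e-14 and adjusted p = 0.0118 with an estimated correlation. Of the pericentral hepatocyte markers, 4 of 10 rose (6 adjusted over the list alone), with adjusted p = 6.96e-07 by camera and adjusted p = 0.0118 with an estimated correlation. They included *Slc1a2*, a glutamate transporter, at 1.69 ± 0.23, *Oat* (ornithine aminotransferase) at 1.09 ± 0.23 and *Cyp1a2* at 0.76 ± 0.16. In the cell cycle list, 8 of 27 genes fell (15 adjusted over the list alone), *Ccnb2* at -1.02 ± 0.18 and *Ccna2* at -0.96 ± 0.27; *Ccna2* lost its call after quantile normalization (adjusted p = 0.0518) and without any one of C replicates 1, 2, 3, 4 and 5 and T20 replicates 2, 4 and 5 (adjusted p 0.0371 to 0.0912 over the arrays left out). The camera result of the list (adjusted p = 1.54e-08) became adjusted p = 0.269 with an estimated correlation. The list of fatty acid oxidation genes and PPAR-alpha targets is called the fatty acid oxidation list below. In it 4 of 35 genes fell (8 adjusted over the list alone), among them *Pdk4*, an inhibitor of pyruvate dehydrogenase, at -1.49 ± 0.30 and *Angptl4*, an inhibitor of lipoprotein lipase, at -1.25 ± 0.23. The others were *Acot2* and *Acadl*, and *Acadl* lost its call without any one of 6 arrays (adjusted p 0.0234 to 0.124 over the arrays left out). That list had adjusted p = 4.4e-05 by camera and adjusted p = 0.269 with an estimated correlation. Amino acid catabolism had 5 of 44 genes higher (5 adjusted over the list alone), *Oat* among them, with adjusted p = 4.4e-05 by camera and adjusted p = 0.269 with an estimated correlation. In xenobiotic metabolism 5 of 33 genes rose and 1 fell (6 and 1 adjusted over the list alone), led by *Fmo1*, a flavin monooxygenase, at 2.04 ± 0.18. That list had adjusted p = 0.000491 by camera and adjusted p = 0.203 with an estimated correlation. The list of male-biased liver genes had 1 of 16 genes higher (4 adjusted over the list alone), with adjusted p = 0.000494 by camera and adjusted p = 0.269 with an estimated correlation.

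Cholesterol synthesis shifted down by camera (median -0.20, adjusted p = 0.0489; adjusted p = 0.765 with an estimated correlation). By limma 0 of its 21 genes passed over all genes, 2 fell when adjusted over the list alone, and 6 had an unadjusted p under 0.05. With equal median and spread of the arrays, the cholesterol and fatty acid oxidation lists were no longer called (camera adjusted p = 0.273 and 0.194). Camera called none of the other lists, but after quantile normalization it called female-biased genes (adjusted p = 0.034), and with equal median and spread bile acid metabolism and acute phase (0.0107 and 0.00578). In sterol efflux and lipoproteins 2 of 31 genes rose and 1 fell (2 and 1 adjusted over the list alone): *Abcg5*, *Abcg8* and *Mttp*, which loads lipid onto apolipoprotein B and fell, at -0.38 ± 0.08. Acute phase had 2 of 33 genes higher (2 adjusted over the list alone), *A2m* by 1.62 ± 0.37 and *Orm1* by 0.73 ± 0.16. Female-biased genes had 2 of 9 lower (4 adjusted over the list alone), with *Prlr*, the prolactin receptor, at -1.43 ± 0.33. Bile acid metabolism had 1 of 23 genes higher (5 higher and 1 lower adjusted over the list alone). The amino acid response had 2 of 31 lower (2 higher and 3 lower adjusted over the list alone), and the clock list 2 of 18 lower (3 adjusted over the list alone). Of these *Clock* lost its call without any one of C replicate 1 and T20 replicates 1 and 5 (adjusted p up to 0.0871). *Npas2* lost its call without any one of C replicates 2, 3 and 5 and T20 replicates 1, 2 and 5 (up to 0.0984), and after quantile normalization (0.0671). *Dbp* was 12.06 in T20 replicate 5 and 7.1 to 9.15 in the other T20 livers. The glucose list had 1 of 21 lower (1 adjusted over the list alone), *Mlxipl*, a carbohydrate-responsive transcription factor, at -0.59 ± 0.12. The glutathione list had 1 of 25 higher (1 adjusted over the list alone) and the stress list 1 of 32 higher (0 adjusted over the list alone). Of the markers of other cells, 1 of 14 macrophage, 1 of 11 endothelial, 1 of 15 stellate and 1 of 3 pancreatic genes rose (1, 2, 1 and 1 adjusted over the list alone), and 1 of 2 intestine and kidney genes fell (1 higher and 1 lower adjusted over the list alone). Among these were *Rgs5* at 0.77 ± 0.13 and *Fabp2*, the intestinal fatty acid binding protein, at -0.94 ± 0.22. By limma 0 of the 7 lymphocyte, 4 bile duct, 8 blood, 6 adipose and 10 periportal genes passed, and 2, 1, 1, 1 and 1 had an unadjusted p under 0.05; adjusted over the list alone, 1 lymphocyte gene was higher and 1 bile duct gene lower. Median and mean differed in sign for the acute phase (-0.03 and 0.02), clock (-0.01 and 0.04) and bile duct (0.11 and -0.59) lists, and camera's direction for sterol efflux was down with a median of 0.01 and a mean of 0.05. The other leading genes were *Acsm3*, a medium-chain acyl-CoA synthetase, at 2.10 ± 0.57, *Inmt*, a methyltransferase, at 2.08 ± 0.45, *Sult1c2*, a sulfotransferase, at 1.91 ± 0.39, *Pcp4l1* at 1.75 ± 0.35 and *Ddhd1*, a phospholipase, at -1.43 ± 0.20.

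Of 18625 probe sets, 839 differed between T20 and C at an adjusted p under 0.05, 328 higher and 511 lower. The split of directions depended on scaling: it was 485 higher and 368 lower after centring each array on its median, and 938 higher and 375 lower with equal median and spread. The count was 389 without C replicate 3, 389 without T20 replicate 1, 421 without T20 replicate 2, 516 without C replicate 5, 383 without C replicate 3 and CI replicate 3 (whose labels give identical normalization parameters), 213 from the T20 and C arrays alone, and 1443 without replicates 4 and 5 of both tofu groups. Of 50 genes of the naming rule that passed, 30 passed whichever array was left out; *Acsm3* lost its call without any one of C replicates 1, 4 and 5 and T20 replicates 2 and 5 (adjusted p 0.0282 to 0.0899).

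**Figure D1:**
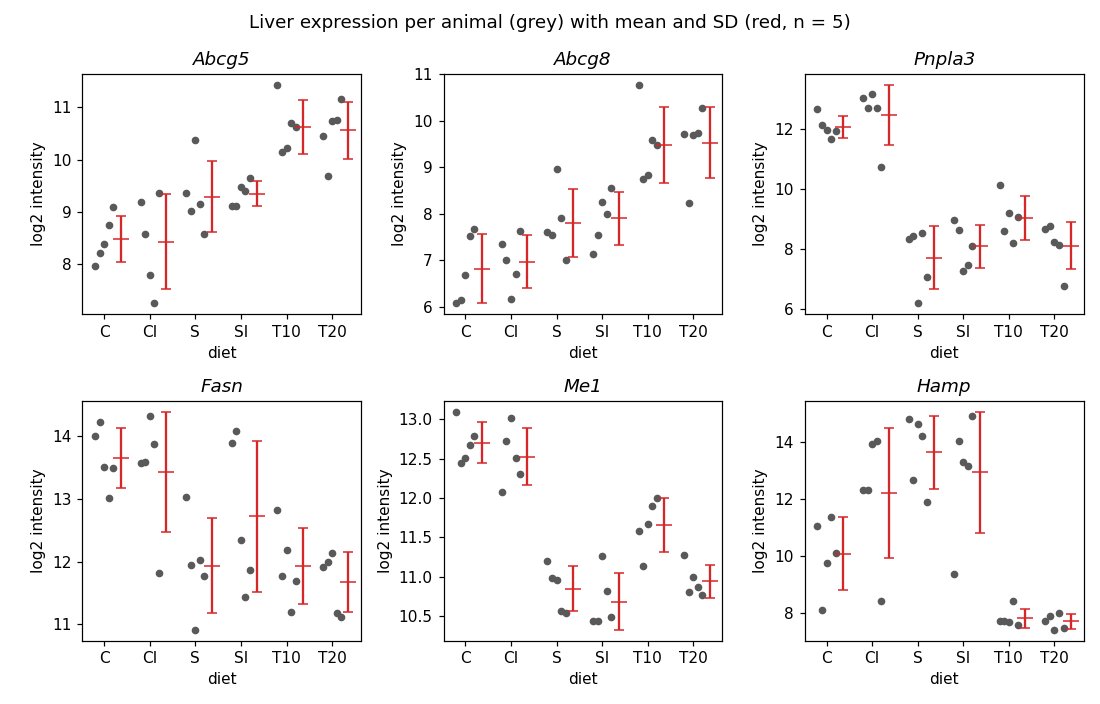
Log2 intensity of 6 genes in each liver (grey points), by diet on the horizontal axis, with the mean and SD of 5 animals in red. Abcg5 averaged 8.47 in C and 10.56 in T20, Pnpla3 averaged 12.08 in C and 8.11 in T20, and Hamp lay between 7.41 and 8.41 in the 10 tofu livers.

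**Figure D2:**
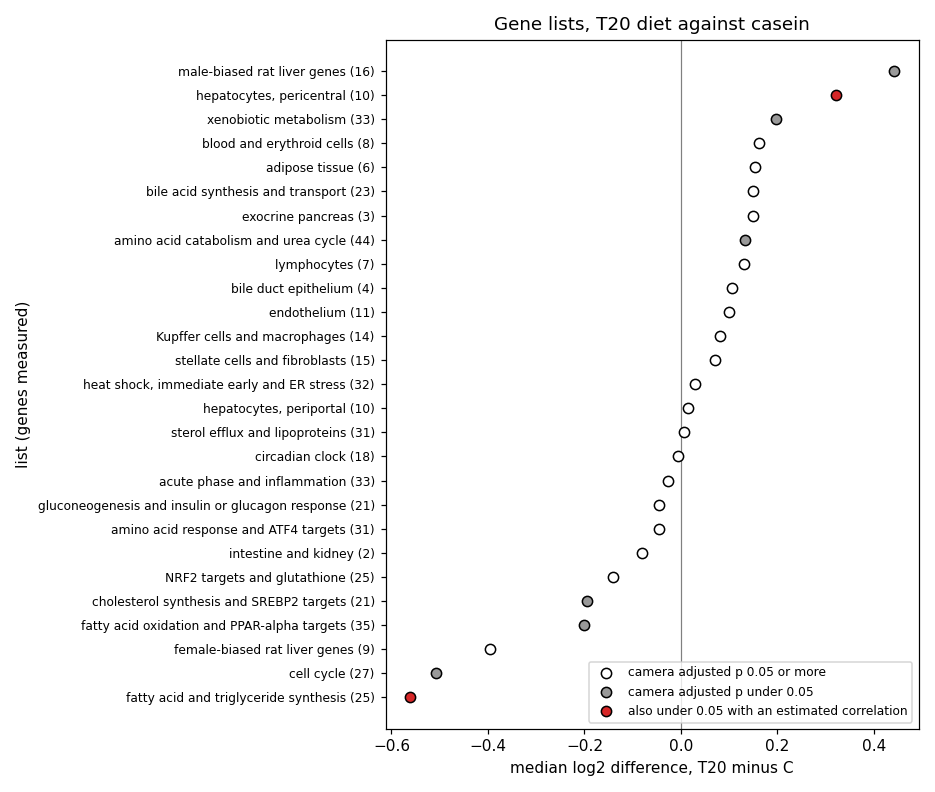
Median log2 difference between T20 and C for each of 27 gene and cell type lists (points), with the number of measured genes in brackets and fill by camera result. As deposited, the median was lowest for fatty acid and triglyceride synthesis (-0.56), and it was negative under each scaling. With equal median and spread it was -0.339, and cell cycle was lowest (-0.392). The sign of the median changed under a scaling for 6 lists that camera did not call, periportal markers among them (-0.002 after quantile normalization).

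Tofu as part of the protein was compared with casein through T10. *Abcg8*, *Abcg5* and *Fmo1* rose by 2.67 ± 0.42, 2.15 ± 0.35 and 2.04 ± 0.18, and *Pnpla3* and *Me1* fell, at -3.03 ± 0.47 and -1.05 ± 0.19. *Plin3*, a lipid droplet coat protein, fell, at -0.95 ± 0.13, and *Acot4*, an acyl-CoA thioesterase, at -1.08 ± 0.21. Among the other leading genes *Pcp4l1*, *Cd14*, *Slc1a2*, *Ces1d* (a carboxylesterase) and *LOC102554026* rose, by 1.90 ± 0.35, 1.21 ± 0.21, 1.19 ± 0.23, 0.90 ± 0.16 and 1.07 ± 0.15. *Irs3*, *Fabp2*, *Ddhd1* and *Hectd2* fell, at -1.20 ± 0.25, -1.12 ± 0.22, -1.02 ± 0.20 and -0.92 ± 0.20. *Fasn* at -1.72 ± 0.47, *Scd* at -0.78 ± 0.28, *Acaca* at -0.70 ± 0.18, *Srebf1* at -0.83 ± 0.36, *Cyp7a1* at 0.34 ± 0.59 and *Cpt1a* at 0.07 ± 0.29 did not pass (adjusted p = 0.134, 0.329, 0.114, 0.432, 0.894 and 0.96). In the fatty acid synthesis list 4 of 25 genes fell (14 adjusted over the list alone; camera adjusted p = 5.86e-11; adjusted p = 0.0138 with an estimated correlation). Xenobiotic metabolism had 3 of 33 genes higher and the pericentral markers 2 of 10 (5 and 5 adjusted over the list alone), with adjusted p = 0.0138 and 0.00551 with an estimated correlation. The bile acid list shifted up by camera (adjusted p = 0.000235; adjusted p = 0.0181 with an estimated correlation); by limma 0 of its 23 genes passed and 6 had an unadjusted p under 0.05. Camera also called cell cycle and fatty acid oxidation down (medians -0.40 and -0.15), with adjusted p = 0.165 and 0.2 with an estimated correlation. It called amino acid catabolism, male-biased genes, endothelium and exocrine pancreas up (medians 0.07, 0.29, 0.12 and 0.23), with adjusted p = 0.275, 0.141, 0.2 and 0.141 with an estimated correlation. Acute phase and sterol efflux were called up too (medians 0.11 and 0.09; adjusted p = 0.141 and 0.293 with an estimated correlation), and after quantile normalization the median of sterol efflux was -0.001. Quantile normalization ended the calls of sterol efflux, acute phase and amino acid catabolism (camera adjusted p = 0.929, 0.828 and 0.325), and equal median and spread those of fatty acid oxidation and exocrine pancreas (0.141 and 0.103). The means of *Abcg8*, *Pcp4l1* and *Slc1a2* in C and of *Hectd2* in T10 lay below the filter level for dim probe sets.

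By limma 60 probe sets differed between T10 and C, 24 higher and 36 lower, against 32 higher and 28 lower with each array centred on its median, and 23 higher and 20 lower with equal median and spread. The 3' to 5' ratio of the GAPDH control probe sets was 1.32 to 1.58 in T10 replicates 3, 4 and 5 and 0.97 to 1.25 in the other 27 arrays. The ratio of the beta-actin control probe sets did not set those 3 arrays apart. It was 2.43, 2.37 and 2.35 in them, within the 1.84 to 2.89 of the other arrays. With those 3 arrays left out 11 probe sets passed. Some leading genes had passed in all 4 diets of soy protein or tofu. Without those arrays *Fmo1*, *Me1* and *LOC102554026* still did so, and *Pnpla3*, *Pcp4l1*, *Ces1d*, *Slc1a2*, *Irs3* and *Ddhd1* did not. Only T10 replicates 1 and 2 then remained, so these losses cannot tell an effect of the left-out arrays from that of fewer livers. The count was 34 from the T10 and C arrays alone, 94 with array weights and 25 without replicates 4 and 5 of both tofu groups. It was 36, 27, 32, 30 and 36 without C replicate 1, C replicate 3, T10 replicate 2, T10 replicate 4 and T10 replicate 5, and 27 without C replicate 3 and CI replicate 3. *Slc1a2* lost its call without any one of C replicate 3 and T10 replicate 2 (adjusted p up to 0.0522), *Irs3* without any one of C replicates 1, 2 and 4 and T10 replicates 2, 4 and 5 (0.101), *Fabp2* without any one of C replicates 1 and 3 and T10 replicate 5 (0.0757), *Acot4* without any one of C replicates 1 and 3 (0.0658), *Ddhd1* without any one of C replicates 1 and 5 and T10 replicates 2 and 5 (0.0754) and *Hectd2* without any one of C replicates 1, 2 and 3 and T10 replicates 1, 3 and 4 (0.12).

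The 2 amounts of tofu were compared directly. Between T20 and T10 limma gave 0 probe sets at an adjusted p under 0.05, with 1318 at an unadjusted p under 0.05 where 931 would arise by chance. The genes with the smallest p were *Hectd2* (1.13 ± 0.20), *Gpt* (alanine aminotransferase, 1.17 ± 0.22) and *Rgs5* (0.60 ± 0.13), with adjusted p = 0.0774, 0.115 and 0.282. Cholesterol synthesis and fatty acid synthesis lay lower with T20 by camera (medians -0.22 and -0.18), with adjusted p = 0.608 and 0.537 with an estimated correlation. Camera also called sterol efflux, female-biased genes and acute phase down (medians -0.07, -0.16 and -0.11), with adjusted p = 0.589, 0.537 and 0.589 with an estimated correlation, and quantile normalization ended these calls (camera adjusted p = 0.356, 0.109 and 0.737). With equal median and spread amino acid catabolism was called (0.00117). The mean of *Hectd2* in T10 lay below the filter level. *Hectd2* passed without T10 replicate 2 (adjusted p = 0.0382; up to 0.309 without another array) and as the mean of its probe sets (0.0404). Leaving out T10 replicate 2, T20 replicate 5, or every array but those of T20 and T10 gave 1 probe set each.

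Soy protein without added isoflavone was compared with casein. The lipogenic genes *Pnpla3*, *Me1* and *Fasn* fell with S, and *A2m*, *Hamp*, *Mat2a* and *Asns* rose. *Pnpla3* fell, at -4.36 ± 0.47, *Me1* at -1.85 ± 0.19 and *Fasn* at -1.72 ± 0.47. *A2m* (alpha-2-macroglobulin) rose by 3.77 ± 0.37 and *Hamp*, which encodes the iron hormone hepcidin, by 3.56 ± 0.87. *Mat2a*, a methionine adenosyltransferase, rose by 2.31 ± 0.18, and *Asns* (asparagine synthetase) by 1.67 ± 0.24. *Scd* at -0.49 ± 0.28, *Acaca* at -0.55 ± 0.18, *Srebf1* at -0.70 ± 0.36, *Cpt1a* at -0.45 ± 0.29, *Cyp7a1* at 0.92 ± 0.59, *Abcg5* at 0.82 ± 0.35 and *Abcg8* at 0.98 ± 0.42 did not pass. *Acaca* passed without S replicate 1 (adjusted p 0.0451 to 0.134 over the arrays left out) and as the mean of its probe sets (0.0213). The other leading genes that rose were *Serpina7* (thyroxine-binding globulin) at 3.29 ± 0.53, *Pcp4l1* at 2.31 ± 0.35, *Sult1c2* at 2.21 ± 0.39, *Fmo1* at 2.05 ± 0.18 and *Nim1k* at 1.88 ± 0.36. Those that fell were *Onecut1*, a hepatic transcription factor, at -3.50 ± 0.89, *Prlr* at -2.07 ± 0.33, *Ddhd1* at -1.80 ± 0.20, *Stac3* at -1.69 ± 0.42 and *Socs2*, a growth hormone target, at -1.60 ± 0.46. The means of *Serpina7*, *Pcp4l1* and *Abcg8* in C lay below the filter level for dim probe sets.

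Fatty acid synthesis had 10 of 25 genes lower and 1 higher with S (15 and 1 adjusted over the list alone; camera adjusted p = 1.13e-07; adjusted p = 0.172 with an estimated correlation). Cholesterol synthesis had 6 of 21 genes lower (8 adjusted over the list alone), *Lss* (lanosterol synthase) at -1.26 ± 0.29 and *Stard4* at -0.86 ± 0.15 (adjusted p = 0.0839 as the mean of its probe sets). Its camera result (adjusted p = 0.00173) became adjusted p = 0.864 with an estimated correlation. The amino acid response list had 3 of 31 genes higher and 1 lower (7 and 3 adjusted over the list alone), with *Aldh18a1*, a proline synthesis enzyme, at 1.04 ± 0.14. That list had adjusted p = 0.0299 by camera and adjusted p = 0.859 with an estimated correlation. Female-biased genes had 4 of 9 lower (4 adjusted over the list alone), with adjusted p = 0.0419 by camera and adjusted p = 0.446 with an estimated correlation. Centring on the median ended the call of the amino acid response list (camera adjusted p = 0.0588). Acute phase was not called, with 3 of 33 genes higher and 1 lower (4 and 1 adjusted over the list alone). Acute phase was called with equal median and spread (camera adjusted p = 0.028), and fatty acid oxidation, amino acid catabolism and the glutathione list after quantile normalization (0.00456, 0.0176 and 0.0176). As deposited, amino acid catabolism was not called by camera, with 6 of 44 genes lower and 1 higher (10 and 2 adjusted over the list alone), *Oat* at -1.14 ± 0.23 and *Cbs* (cystathionine beta-synthase) at -0.86 ± 0.15. By limma 1351 probe sets differed between S and C, 556 higher and 795 lower. The directions were 761 higher and 603 lower after quantile normalization, 763 and 528 after centring on the median, and 751 and 405 with equal median and spread. Without S replicate 2 the count was 898. *Fasn* lost its call without any one of C replicates 1 and 2 and S replicate 3 (adjusted p 0.0108 to 0.0681) and *Socs2* without any one of C replicates 1, 3, 4 and 5 and S replicates 1 and 2 (0.00987 to 0.114).

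Added isoflavone was tested on each protein. On casein, limma gave 0 probe sets for CI against C at an adjusted p under 0.05 and 1605 at an unadjusted p under 0.05. The genes with the smallest p were *Bpifa5* (0.97 ± 0.18), *Hsd11b1*, which regenerates active glucocorticoid (0.54 ± 0.10), and *Frmpd2* (1.14 ± 0.23), each with an adjusted p of 0.134, and the mean of *Frmpd2* in C lay below the filter level. Camera called the macrophage, glutathione and cell cycle lists down (medians -0.26, -0.16 and -0.19) and male-biased genes up (0.15), with adjusted p = 0.9 for each with an estimated correlation, and equal median and spread ended the call of the glutathione list (0.107). Equal median and spread also added calls of fatty acid oxidation, sterol efflux, amino acid catabolism, xenobiotic metabolism, acute phase and periportal markers (camera adjusted p = 0.000345, 0.0233, 5.76e-06, 0.0152, 0.000345 and 0.0146), and quantile normalization added cholesterol synthesis (0.0359). *Hsd11b1* passed without C replicate 5 (adjusted p 0.0175 to 0.425 over the arrays left out). The count was 1 without C replicate 1, 3 without C replicate 5, 4 with array weights and 1 with no filter on dim probe sets. On soy protein, limma gave 0 probe sets for SI against S and 664 at an unadjusted p under 0.05. *Dzip1l* (-2.07 ± 0.51), *Hpd* (4-hydroxyphenylpyruvate dioxygenase, 0.27 ± 0.07) and *Kcns2* (-1.84 ± 0.49) had the smallest p, with adjusted p of 0.999 for each. Camera called amino acid catabolism and periportal markers up (medians 0.15 and 0.15; adjusted p = 0.164 for both with an estimated correlation). It also called cholesterol synthesis, fatty acid synthesis and the glutathione list up (medians 0.15, 0.11 and 0.12), with adjusted p = 0.76 for each with an estimated correlation. Quantile normalization ended the calls of fatty acid synthesis, glutathione and periportal lists (camera adjusted p = 0.235, 0.143 and 0.202) and added acute phase (0.0386), and centring on the median added the intestine and kidney list (0.0474). The isoflavone effect itself differed between the proteins for 3 probe sets, those of *Kcns2* (-4.01 ± 0.69) and *Bpifa5* (-1.43 ± 0.26) and 1 with no named gene (-2.79 ± 0.47), each more negative on soy protein. The means of *Dzip1l* and *Kcns2* in SI lay below the filter level. So did that of *Kcns2* in C, and those of the probe set with no named gene in C and SI. *Endog* came next by p among named genes and did not pass (-0.71 ± 0.15). For the interaction camera called cholesterol synthesis and the glutathione list up (medians 0.34 and 0.29), with adjusted p = 0.876 and 0.618 with an estimated correlation. Equal median and spread added fatty acid oxidation, male-biased genes and acute phase (camera adjusted p = 0.00523, 0.0223 and 0.0128). After quantile normalization 1 probe set was higher and 3 were lower. The count was 0 without any one of C replicates 2 and 4, CI replicates 1, 3, 4 and 5, S replicates 2, 4 and 5 and SI replicates 1, 4 and 5, 1 without SI replicate 2, 5 without C replicate 1, 1 from the compared arrays alone, 0 without C replicate 3 and CI replicate 3 and 0 above the 60th percentile of mean level. *Bpifa5* also lost its call without C replicate 5 or SI replicate 3 (adjusted p 0.032 to 0.119 over the arrays left out), and *Kcns2* ranged from 0.00224 to 0.0928.

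Soy protein with isoflavone was compared with casein through SI. *A2m*, *Mat2a* and *Fmo1* rose by 3.49 ± 0.37, 2.35 ± 0.18 and 2.04 ± 0.18, and *Pnpla3*, *Me1* and *Prlr* fell, at -3.99 ± 0.47, -2.02 ± 0.19 and -2.08 ± 0.33. *Hamp* rose by 2.86 ± 0.87, *Serpina7* by 2.39 ± 0.53, *Sult1c2* by 1.91 ± 0.39, *Pcp4l1* by 1.90 ± 0.35 and *Cyfip2* by 1.81 ± 0.26. *Cdh8* fell, at -2.72 ± 0.69, *Pllp* at -1.88 ± 0.52, *Ddhd1* at -1.75 ± 0.20, *Irs3* at -1.63 ± 0.25 and *Pdk4* at -1.62 ± 0.30. *Fasn* at -0.93 ± 0.47, *Scd* at -0.51 ± 0.28, *Acaca* at -0.31 ± 0.18, *Srebf1* at -0.27 ± 0.36, *Cpt1a* at -0.75 ± 0.29, *Cyp7a1* at 0.98 ± 0.59, *Abcg5* at 0.88 ± 0.35 and *Abcg8* at 1.08 ± 0.42 did not pass, and *Cpt1a* passed without SI replicate 5 (adjusted p 0.044 to 0.273 over the arrays left out). Fatty acid synthesis had 5 of 25 genes lower and 1 higher (9 and 1 adjusted over the list alone; camera adjusted p = 0.000176; adjusted p = 0.417 with an estimated correlation). The amino acid response list had 3 of 31 genes higher and 1 lower (7 and 2 adjusted over the list alone), *Asns* by 1.34 ± 0.24, with adjusted p = 0.0114 by camera and adjusted p = 0.511 with an estimated correlation. Female-biased genes had 3 of 9 lower (5 adjusted over the list alone; camera adjusted p = 0.00547; adjusted p = 0.2 with an estimated correlation). The pericentral list had 3 of 10 genes higher and 1 lower (4 and 2 adjusted over the list alone), with adjusted p = 0.0402 by camera, 0.232 after quantile normalization, and adjusted p = 0.511 with an estimated correlation. Acute phase had 3 of 33 higher and 1 lower (3 and 1 adjusted over the list alone) and was called up (median 0.10; adjusted p = 0.572 with an estimated correlation), while its median was -0.009 and its camera adjusted p 0.865 after quantile normalization, which added calls of cholesterol synthesis and fatty acid oxidation (0.0369 and 0.000175). The means of *Serpina7*, *Pcp4l1* and *Abcg8* in C and of *Cdh8* and *Pllp* in SI lay below the filter level. By limma 1337 probe sets differed, 650 higher and 687 lower; the directions were 838 and 471 after quantile normalization, 1051 and 419 after centring on the median, and 972 and 346 with equal median and spread. Without C replicate 1 the count was 846 and without SI replicate 5 it was 836. *Hamp* lost its call without any one of C replicates 1, 2, 3 and 5 and SI replicates 2, 3, 4 and 5 (adjusted p 0.0034 to 0.131), *Cdh8* without SI replicate 2 (0.0517) and *Pllp* without any one of C replicates 1, 2, 3 and 5 and SI replicates 1 and 4 (up to 0.0741).

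Tofu was set against soy protein at a matched isoflavone level through T20 and SI. *Hamp* was lower with T20 at -5.23 ± 0.87, and *A2m*, *Mat2a* and *Asns* fell, at -1.87 ± 0.37, -1.48 ± 0.18 and -1.14 ± 0.24. *Oat* rose by 1.93 ± 0.23, *Inmt* by 3.17 ± 0.45 and *Abcg8* by 1.63 ± 0.42. *Alox15*, a lipoxygenase, *Acsl4*, an acyl-CoA synthetase for polyunsaturated fatty acids, *Cela1*, *Mtmr7* and *Il33* rose by 1.89 ± 0.32, 1.24 ± 0.18, 1.13 ± 0.19, 1.05 ± 0.24 and 1.01 ± 0.23. *Aldh1b1*, *Aldh1a1*, *Cdkn1a* (the cell cycle inhibitor p21), *Abca4* and *Gfra3* fell, at -1.64 ± 0.20, -1.32 ± 0.31, -1.52 ± 0.43, -1.19 ± 0.28 and -1.17 ± 0.14. The amino acid response list had 5 of 31 genes lower (6 adjusted over the list alone; camera adjusted p = 0.00223; adjusted p = 0.43 with an estimated correlation). Bile acid metabolism had 2 of 23 genes higher (8 adjusted over the list alone), *Baat*, which conjugates bile acids, by 0.52 ± 0.10, with adjusted p = 0.0105 by camera and adjusted p = 0.416 with an estimated correlation. Cell cycle had 3 of 27 genes lower (3 adjusted over the list alone), among them *Ccnd1* at -0.96 ± 0.18 and the inhibitor *Cdkn1a*. That list had adjusted p = 7.13e-06 by camera and adjusted p = 0.43 with an estimated correlation. Fatty acid synthesis had 4 of 25 genes lower and 1 higher (7 and 1 adjusted over the list alone), *Pklr* (liver pyruvate kinase) at -0.64 ± 0.14 and *Agpat2* at -0.63 ± 0.11, with adjusted p = 0.00649 by camera and adjusted p = 0.43 with an estimated correlation. Acute phase had 1 of 33 genes higher and 2 lower (1 and 2 adjusted over the list alone) and was called down (median -0.11; adjusted p = 0.43 with an estimated correlation), with a median of 0.013 and a camera adjusted p of 0.701 after quantile normalization. Equal median and spread ended the call of fatty acid synthesis (0.0683), and quantile normalization added xenobiotic metabolism and male-biased and female-biased genes (0.00352, 0.00205 and 0.0261). Camera also called amino acid catabolism, macrophage, endothelial and pericentral lists up (medians 0.17, 0.21, 0.09 and 0.30; 2, 1, 1 and 1 genes higher over all genes, 8, 1, 2 and 3 adjusted over the list alone), with adjusted p = 0.43 for each with an estimated correlation. The mean of *Abca4* in T20 lay below the filter level. By limma 653 probe sets differed, 304 higher and 349 lower, against 254 higher and 462 lower after centring on the median. The count was 228, 1026, 432, 397, 268 and 382 without SI replicate 2, SI replicate 3, SI replicate 4, SI replicate 5, T20 replicate 1 and T20 replicate 2, 39 from the T20 and SI arrays alone, and 1249 without replicates 4 and 5 of both tofu groups. Of 45 genes of the naming rule that passed, 21 passed whichever array was left out. *Abcg8* lost its call without any one of SI replicates 1 and 2 and T20 replicates 1, 3 and 5 (adjusted p up to 0.0809), *Cdkn1a* without any one of SI replicates 1, 2, 4 and 5 and T20 replicates 2, 4 and 5 (0.113), *Aldh1a1* without any one of SI replicates 2 and 5 and T20 replicate 1 (0.0559), *Mtmr7* and *Abca4* without SI replicate 5 (0.0535 and 0.0512), *Pklr* without SI replicate 2 (0.0543) and *Il33* without T20 replicate 1 (0.0514).

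Differences from the same 5 casein livers were compared between diets. Those of T20 and S correlated across probe sets at r = 0.611, where unchanged groups against shared controls gave 0.498 in simulation, and their covariance was 0.0483 against 0.0155. Of the changed probe sets 125 were higher and 202 lower in both, and 4 moved in opposite directions; independent lists, which these are not, would share 9.8 and 21.8. With the controls split between the comparisons the mean r over 20 splits was 0.332 (0.297 to 0.4) and the mean covariance 0.0319, with medians of 26.5 higher and 38.5 lower in both from fewer control livers. For T20 and T10 r was 0.7 (0.502 simulated) and the covariance 0.0426 (0.0158 simulated), with 18 probe sets higher and 31 lower in both against 0.4 and 1 for independent lists; split controls gave a mean r of 0.337 and medians of 5 and 6.5. For S and SI r was 0.796 (0.497 simulated) and the covariance 0.0662 (0.0154 simulated), with 424 higher and 421 lower in both against 19.4 and 29.3, and split controls gave a mean r of 0.498 and medians of 135 and 98.5. Probe sets are not independent replicates. No probe set passed in both members of a pair in the simulations without effects, which drew each probe set independently.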

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

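The values in this part come from checks fixed before the data were examined, except that the genes checked depend on which passed. Among the named genes, 405 sets of 5 livers were examined for a single liver far from the rest of its diet, and 20 were found where chance gives 20.2. With T20, *Abcg8* in replicate 2 lay -1.62 from the mean of the other 4 livers, *Slc1a2* in replicate 1 1.24, *Asns* in replicate 1 -0.79, *Vnn1* in replicate 5 -0.79, *Cpt1a* in replicate 5 1.29 and *Mcm7* in replicate 3 0.28. With T10, *Pcp4l1* and *Gpt* in replicate 1 lay at -1.6 and -0.92. With casein, *Mat2a* in replicate 1 lay at 0.75, *Stac3* in replicate 3 at -2.04, *Pllp* in replicate 4 at -2.01, *Bpifa5* in replicate 5 at -0.72 and *Glul* in replicate 2 at -0.36. With S, *Oat* and *Cidea* in replicate 4 lay at 0.26 and 0.69, *Dzip1l* in replicate 1 at -1.2 and *Orm1* in replicate 3 at -0.3, with CI *Kcns2* in replicate 2 at -1.24, and with SI *Gpd1* in replicate 2 at 0.53 and *Glul* in replicate 5 at 0.32.

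The effect of isoflavone differed between soy protein and casein, by limma's test of the difference, for *Kcns2* (-4.01), *Bpifa5* (-1.43) and a probe set without a named gene (-2.79). Mean log2 values of *Kcns2* were 7.21 in C, 9.39 in CI, 8.63 in S and 6.8 in SI, and those of *Bpifa5* were 7.95, 8.91, 8.6 and 8.14. *Kcns2* and the probe set without a named gene averaged below the level of the dim filter in C and SI.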

How the results depend on the processing

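Floors, leaving out T10 replicates 3, 4 and 5, and leaving out replicates 4 and 5 of both tofu groups were chosen after seeing the data. Counts stayed within 1.5 times under quantile normalization, median centring, no variance trend, a minimum difference and floors of 1 and 64. With equal median and spread T20 against C gave 1313; the cause was not tested. Without the dim filter CI against C gave 1, and above the 60th percentile the interaction gave 0. From the compared groups alone T20 against C gave 213, T10 against C 34, T20 against T10 1, the interaction 1 and T20 against SI 39. S against C gave 1083 and SI against C 936 there, with equally few samples. The falls were larger with T20, but T20 against C also kept a smaller share of its calls at an adjusted p under 0.01. There 216 of 839 probe sets remained, against 590 of 1351 for S against C. Whether fewer samples alone account for the larger falls was therefore not settled. The T20 counts of the main fit rest on a spread estimated from all 30 arrays. Array weights gave 94 for T10 against C and 4 for CI against C. An adjusted p under 0.01, stricter by construction, gave 216 for T20 against C, 24 for T10, 590 for S, 470 for SI, 0 for the interaction, 138 for T20 against SI and 1141 for any diet. Without C replicate 3 and CI replicate 3 T20 against C gave 383, T10 against C 27 and the interaction 0. T10 against C gave 11 without T10 replicates 3, 4 and 5, which left only T10 replicates 1 and 2. Without replicates 4 and 5 of both tofu groups T20 against C gave 1443, T10 against C 25 and T20 against SI 1249, and 623 of the 839 probe sets of T20 against C passed there too. Counts with 1 array left out ran from 389 to 1029 for T20 against C, 27 to 69 for T10, 0 to 1 for T20 against T10, 898 to 1302 for S, 0 to 3 for CI, 836 to 1297 for SI, 0 to 5 for the interaction and 228 to 1026 for T20 against SI. List calls over all comparisons fell from 54 to 6 with an estimated correlation and 23 by fry. By quantile normalization the acute phase list turned from up to down in SI against S (median -0.055) and SI against C (-0.009) and from down to up in T20 against SI (0.013), and *Rup2* in SI against C turned to -0.296 as the mean of its probe sets. Apart from the settings that explain themselves, the cause was not tested. The replicate numbers were not taken to pair the livers: same-number correlations of deviations from the group means averaged 0.045 (-0.011 for other numbers; 0.14 in S against C) and were over 0.1 in 22 of 75 pairs, in no comparison in all 5, and 9 of 30 arrays correlated best with their own number. With the replicate number as a block the counts were 1120, 76, 0, 1693, 0, 0, 1667, 1 and 970 in the order T20, T10, T20 against T10, S, CI, SI against S, SI, interaction and T20 against SI. Probe sets averaging below the filter level of 7.388 were not tested, and signal over background was not measured.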

Other observations

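The tests in this part were chosen after the results were seen, except the spike-in test, the BMP-SMAD test and the splits of the arrays. A small set of genes changed from casein with each of the 4 diets of soy protein or tofu, and most of it depended on single arrays: 24 genes passed the same way in each, 11 higher and 13 lower, out of 43 that passed for T10, and 9 of them did so whichever array of the 5 groups was left out. The number was 14, 14, 12, 11, 13 and 14 without C replicate 1, C replicate 2, C replicate 3, T10 replicate 2, T10 replicate 4 and T10 replicate 5. It was 5 without T10 replicates 3, 4 and 5, whose GAPDH 3' to 5' ratios were high and whose beta-actin ratios were not. Only T10 replicates 1 and 2 remained there. The 24 genes were chosen after their values were seen, and part of the overlap may come from the 5 shared casein livers. The T10 count fell from 60 to 27 without C replicate 3. It also fell to 30 without T10 replicate 4, which is not shared, so such falls do not bear on this. Splitting the controls lowered the r of T20 and T10 from 0.7 to 0.337. Fewer control livers per comparison also lower r. The mean covariance with split controls was 0.0262, near the 0.0268 by which the full covariance exceeded that of unchanged groups. *Fmo1* rose by 2.04 ± 0.18, 2.04 ± 0.18, 2.05 ± 0.18 and 2.04 ± 0.18 for T20, T10, S and SI, with a difference of 0.07 for CI (adjusted p = 0.938 by limma). Its log2 values lay between 12.1 and 13.16 in the 20 livers of those diets and between 10.22 and 11.18 in the 10 casein livers. *Fmo1* and *Me1* were among the 9 and among the 5. *Hsd11b1*, which regenerates active glucocorticoid, *Ces1d* and *Car3* (carbonic anhydrase 3) rose in all 4 and were among the 9, but not among the 5. Differences of CI from C for the 24 genes lay between -0.595 (*Kif20a*) and 0.537 (*Hsd11b1*), with adjusted p of 0.134 or more by limma (0.0175 for *Hsd11b1* without C replicate 5). For 17 of the 24 genes, *Hsd11b1* among them, the soy and tofu livers overlapped with the 10 casein livers.

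Some clock genes differed between replicate numbers within the diets. The mean deviation of *Nr1d1* from its group mean was -1.56 in animals numbered 1 and 1.47 in those numbered 5, and 3 of 18 clock genes (*Nr1d1*, *Nr1d2* and *Cry1*) passed for number against 458 of 10681 other genes (one-sided Fisher's exact p = 0.0401). That test repeats the observation that led to it, so it lends no support to a shared time of collection. With the GAPDH 3' to 5' ratio as a covariate 3 clock genes still passed, while the passing genes fell from 461 to 120. By the limit written for it this counts against RNA degradation as the whole cause. That ratio stood out only in T10 replicates 3, 4 and 5, where the beta-actin ratio did not. It therefore cannot decide the matter for the other diets. Of 45 bacterial spike-in probe sets 42.2% had a p under 0.05 for number, so arrays of 1 number may also have shared a labelling or hybridisation step; spike-ins move together, and a shared time stays open as untested. *Dbp* was 9.65 and 10.97 in T10 replicates 4 and 5, and 9.15 and 12.06 in T20 replicates 4 and 5.

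*Hamp* lay between 7.41 and 8 in T20, between 7.57 and 8.41 in T10, between 9.35 and 14.9 in SI, between 11.91 and 14.79 in S, between 8.42 and 14.04 in CI and between 8.1 and 11.36 in C. Of the T20 minus SI difference of -5.23, 2.86 was the rise of SI over C, and the T20 minus C difference of -2.38 did not pass (adjusted p = 0.111). Every T20 liver nevertheless lay below every C liver. The test used 1 spread for all diets, while the SD was 0.25 in T20, 1.29 in C, 2.27 in CI and 2.13 in SI. The call thus depends in part on diets outside the comparison. A lower iron or BMP-SMAD signal was tested on *Id1*, *Smad6*, *Smad7* and *Atoh8*, whose median T20 minus SI difference was -0.09, with members going both ways. By the limit set beforehand this median counts against that signal. It passes the limit by less than the SE of the mean, 0.056. A lower inflammatory signal was tested on the acute phase list without *Hamp*, with a median of -0.096. *A2m*, which responds to that signal, was lower in T20 than in SI by 1.87. Against casein, however, *A2m* rose with T20 by 1.62 and with SI by 3.49, so it did not move with *Hamp* there. By the limit written for it the list median counts against the signal. The list as written mixes genes that rise in inflammation with genes that fall, such as *Alb* and *Ttr*, so its median cannot decide. Neither value is enough to exclude its signal, and a direct effect of tofu was not tested.

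Pericentral markers rose with T20 by a median of 0.32. If more pericentral tissue had been sampled, periportal markers should have fallen; their median was 0.015 (-0.002 after quantile normalization), with a mean of 0.169 ± 0.174 (SE over 10 genes), a spread that leaves this explanation open. It may also reflect the diet, which was not tested further.

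For chance, arrays were reassigned in 100 splits per comparison, the real one included. Only the real split reached 839 probe sets for T20 against C (highest other 340), 60 for T10 against C (2), 1351 for S against C (40), 1337 for SI against C (35), 653 for T20 against SI (485), 3 for the interaction (2) and 2409 for any diet (1), so 1 of 100 splits, the real one, gave as many. That share is the smallest that 100 splits can give, so chance was made unlikely and was not excluded. For the interaction the margin was 1 probe set. Its count was 0 without any one of C replicates 2 and 4, CI replicates 1, 3, 4 and 5, S replicates 2, 4 and 5 and SI replicates 1, 4 and 5. The highest other split for T20 against C exchanged T20 replicate 5 with C replicate 1, and that for T20 against SI exchanged T20 replicate 5 with SI replicate 3. For T20 against T10, CI against C and SI against S the real count was 0, which each of the 100 splits reaches, so the splits decide nothing there; the highest others were 728, 3 and 2. The split with 728 set T10 replicates 1, 4 and 5 and T20 replicates 4 and 5 against the other tofu livers, which points to a structure of those samples.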
